A study of Mus musculus with 18 samples.

How the data were processed

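RNA was sequenced from 12 B cell lymphomas of mouse spleen and from 6 reference libraries of normal mouse B cells, all on a C57BL/6 background. All lymphomas arose in mice with Cre recombinase under the Cγ1 promoter, which acts in B cells that enter the germinal center reaction, and with a Bcl6 transgene. In 7 of them (NIK_Bcl6 lymphomas) the mice also carried a transgene for NIK, the kinase of the alternative NF-κB pathway encoded by Map3k14, and in 5 (Bcl6 lymphomas) they did not. The references were resting splenic CD19+ B cells, CD19+ cells cultured for 24 h with anti-CD40 and anti-IgM (ABC), and YFP+ germinal center B cells taken at day 10 (GCB), with 2 libraries each. The labels give the lymphomas 12 different tumor numbers, which were taken as 12 separate mice. Replicates of a reference share 1 control number in their titles and are not described here as separate animals.

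The submitters' processing notes name TopHat, HTSeq and edgeR and the builds NCBIM37 and mm9, without versions, roles or order; the variant caller is not given in the sources used here. The values came from 1 deposited table with 3 header lines and 4274 candidate variant positions on NCBI 37, each with the expression of its gene. Allele values are the fraction of reads with the alternative allele, per the file headers. Each lymphoma also has a deposited p-value for its difference from the control at each position, not adjusted as far as the headers say. The control is the resting B cells, since its allele fractions were equal across lymphomas at 99.6% of positions within a tolerance of 0.001. Expression is given by the authors as a log2 ratio of each lymphoma to the resting B cells and as an RPKM, which scales reads to transcript length and library size. The deposited RPKM proved to be the mean over 1 lymphoma and the 2 resting libraries, because only that reading gave 1 resting level per gene across the lymphomas (median deviation 0.0255 on the log2 scale over 2205 genes). The deposited log2 values of ABC and GCB have the opposite sign, resting over the other group, and were turned around. The level of each lymphoma and each pooled reference was recovered from the RPKM and the log2 value. Reads per library and coverage per position are not given, so the depth is unknown and no counting interval was computed. The 3 per-sample columns that repeat reference groups were not used.

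Expression was present for 2292 genes, each listed because of a candidate variant, so they are a selected part of the genome. Gene IDs of 2285 were matched to symbols in the reference annotation and 7 were not. For 44 genes the RPKM was not finite, which left 2248, and 2243 had at least 1 RPKM in at least 2 libraries and were tested. Genes that occupied several lines held the same expression values on each.

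The comparisons, gene lists, tests and the adjusted threshold of 0.05 were fixed before the data were examined. The filters of 1 RPKM and the rule for calling a position were not spelled out in that plan. A fit over all 18 libraries in 5 groups had been planned. It was replaced by a fit over the 12 lymphomas because the deposited table pools the replicates of each reference. For the same reason a cut-off of 1 log2 replaced the planned adjusted threshold for the axis genes and for the counts between references. The log2 values were fitted with limma 3.58.1 in R 4.3.3, with a mean-dependent trend taken from the log2 mean RPKM and Benjamini-Hochberg adjustment over the genes at 0.05. Tests against a reference asked whether the mean of the lymphomas departs from the pooled reference value, which was treated as fixed. Their p-values thus measure only the spread between lymphomas, and the error of the reference itself is not in them. Values that compare references with each other carry no test, error or n. Errors are SE for fitted log2 differences and SD for levels and counts. All tests were two-sided.

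Of 19 fixed gene lists, 13 had at least 5 measured genes and were tested with camera at a preset correlation of 0.01, and again with the correlation estimated, adjusted over the lists of a comparison. The lists hold markers or pathway members of germinal center, activated and plasma cells, the alternative NF-κB pathway, NF-κB targets, genes known to be repressed by Bcl6, the cell cycle, Myc and ribosome biogenesis, B cell receptor signalling, antigen presentation, the interferon response and the DNA damage response. Others hold markers of T cells, NK cells, myeloid cells, erythroid cells and stroma or endothelium, genes recurrently mutated in human B cell lymphoma, and known off-target genes of AID, the enzyme of somatic hypermutation. Genes were named by a fixed rule: Bcl6 and Map3k14 always, then the 10 of largest positive and 10 of largest negative difference among those past the threshold and at or above the median level (5 each way against ABC, against resting B cells and between references), and up to 4 members of each list. Where no gene passed, the 5 of smallest p at or above the median level were named as not passing. Predicted genes and immunoglobulin or T cell receptor segments were counted and not named. Lists of variants name the 10 genes hit in the most lymphomas and the members of the lymphoma list with a protein-changing position.

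The ABC-GCB axis of a sample is its mean z value over genes at least 1 log2 higher in ABC than in GCB, minus that over genes at least 1 log2 higher in GCB, with at least 1 RPKM in the higher group. A position counted as called in a lymphoma when its deposited p was under 0.05 and its allele fraction exceeded that of the resting B cells. It counted as the lymphoma's own when no other lymphoma had a call there and no reference showed the allele. A reference without a value at the position was taken as not showing it. Protein-changing positions were those annotated with a different amino acid or a stop, 1806 of the 4274. Differences between lymphoma groups in single values were tested by exact permutation over all 792 splits of 7 and 5, whose smallest possible p is 0.00126. Fisher's exact test compared genotypes for genes hit in at least 3 lymphomas, and lists with the other genes of the table. Carriers of a call were compared with the other lymphomas by permuting carriers within genes 100000 times. Each gene was permuted separately, so these p-values treat genes as independent and do not measure the spread between lymphomas. No paired test was made, since nothing pairs the samples. Shares of transitions and of C-to-T changes were planned and not computed, because the columns used give no bases. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.

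The fits were tested on simulated data with the spread of the real lymphomas and 200 genes changed. Between lymphoma groups 60% of genes changed by 1 log2 and 92% of those changed by 2 were recovered, with 6.17% false calls. For 7 lymphomas against a fixed reference the shares were 83% and 100%, with 3.68% false calls. The simulated noise was independent between genes, unlike real expression. With fewer changed genes the adjusted threshold is harder to reach. These shares may therefore overstate what the real comparisons could detect. A shift of 1 log2 added to carriers was recovered as 1 over 957 genes. That checks only the computation, since the shift enters directly into the difference measured. Alternatives tried were centring each lymphoma on its median, no trend, no filter on low levels, 0.1 or 1 RPKM added before the logarithm, other axis genes and scores, stricter and narrower sets of variants, and leaving out each lymphoma in turn. Added after the data were seen were the alternatives with 1 RPKM, without positions of a BALB flag, without immunoglobulin segments, with an allele fraction of at least 0.2, with calls as a percent of the positions with a value, with the splice-site share, and without the pair of lymphomas with the fewest positions with a value. Also added then were the leaving out of each lymphoma for the protein-changing share, own positions for genes hit in several lymphomas, centring, own positions and their combinations for carriers of a call, and the list tests with protein-changing positions, own positions or without Bcl6.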

Results

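Messenger RNA of 12 mouse spleen lymphomas and 6 libraries of normal B cells was sequenced. The table gives the expression of genes that hold a candidate variant and the allele fraction of each variant in each lymphoma. There were 5 Bcl6 lymphomas, 7 NIK_Bcl6 lymphomas, and 2 libraries each of resting B cells, of B cells activated in culture (ABC) and of germinal center B cells (GCB). Replicates of a reference are pooled in the table, so a reference has 1 value per gene. Sequencing depth is unknown, and 2243 genes were tested. Medians of all genes against a reference lay between −0.19 and −0.10 on the log2 scale, and counts after centring each lymphoma on its own median are given beside the others. Centring changed the sign of 0 of the 318 named gene and comparison pairs past the threshold.

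The comparison of NIK_Bcl6 with Bcl6 lymphomas asks what the NIK transgene adds to lymphomas that share a Bcl6 transgene. Bcl6 is a transcriptional repressor that acts in germinal center B cells. It stood at 157 ± 90.5 RPKM (SD, n = 5) in Bcl6 lymphomas and at 151 ± 107 RPKM (SD, n = 7) in NIK_Bcl6 lymphomas. In the authors' deposited table the pooled Bcl6 level was 37.6 RPKM in resting B cells, 2.67 RPKM in ABC and 78.5 RPKM in GCB. The Bcl6 difference between lymphoma groups was −0.21 log2 (SE 0.61; adjusted p = 0.985 by limma), and it was 0.04 without Bcl6 lymphoma replicate 5 and 0.17 without NIK_Bcl6 replicate 5. Map3k14, which encodes NIK, was not analysed here because it is not among the genes of the table used. Across all genes 0 passed limma's adjusted threshold, 154 had an unadjusted p under 0.05, and the median difference was 0.02 log2. Among genes at or above the median level, predicted genes and immunoglobulin or T cell receptor segments aside, Chka, choline kinase alpha, had the smallest p. It differed by 1.63 log2 (SE 0.31, adjusted p = 0.215 by limma). Raf1 (−0.68, SE 0.17) and Map2k1 (0.57, SE 0.15), kinases of the MAP kinase cascade, did not pass either, each with an adjusted p of 0.522. Neither did Swap70, a signalling protein of B cells (1.04, SE 0.27), nor the helicase gene Helz2 (1.06, SE 0.29).

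Among gene lists, the 12 measured cell cycle genes were lower in NIK_Bcl6 than in Bcl6 lymphomas as a set, with a median of −0.49 log2 (camera adjusted p = 0.00177). That call was lost with the correlation between genes estimated (adjusted p = 0.961 with an estimated correlation), and 0 lists passed without NIK_Bcl6 replicate 6. No cell cycle gene passed alone: Bub1b, a spindle checkpoint kinase, differed by −1.04 log2 (SE 0.31; adjusted p = 0.522) and the proliferation marker Mki67 by −0.65 (SE 0.44; adjusted p = 0.809). Of 8 NF-κB targets 0 passed over all genes and 2 were higher when adjusted over the list alone, Nfkbia, the inhibitor of NF-κB (0.84, SE 0.28), and the adhesion molecule gene Icam1 (0.58, SE 0.17). That list had a median of −0.12 and a mean of −0.02 while its test pointed up (camera adjusted p = 0.941). Antigen presentation genes (median 0.19), interferon response genes (0.34) and the lymphoma-mutated genes (0.20) had an adjusted p of 0.406 each, and Myc and ribosome biogenesis genes (0.17) of 0.705. Bcl6-repressed genes (median 0.20) and DNA damage response genes (0.14) reached an adjusted p of 0.760. Adjusted p was 0.941 for activated B cell genes (median 0.30, mean −0.03, test down), plasma cell genes (0.06), B cell receptor genes (median 0.02, test down), AID targets (−0.09) and myeloid markers (median −0.19, mean 0.06, test down). In no list other than the NF-κB targets did a gene pass over the list alone, and in none over all genes. Too few genes were measured to test the germinal center list (2 genes, median −0.64), the alternative NF-κB pathway (2 genes, −0.46), T cell markers (4 genes, −0.86) and stroma (Nid1 alone, 0.87), and 0 NK or erythroid markers were measured.

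**Figure D1:**
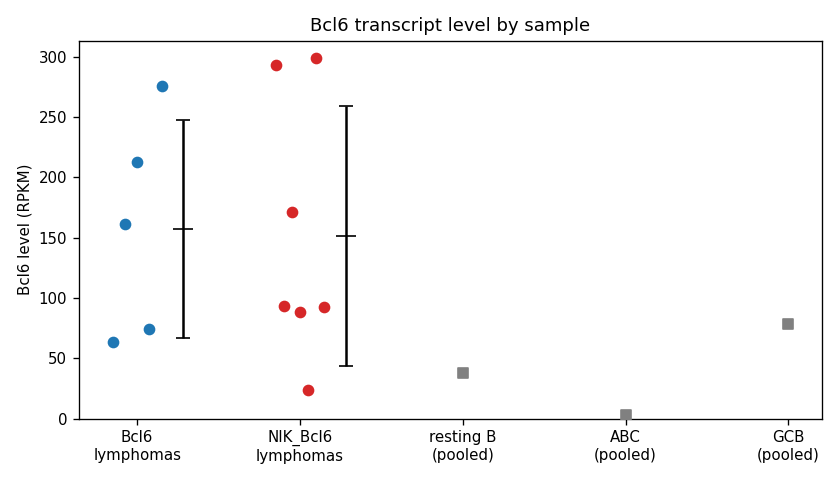
Bcl6 transcript level in RPKM for each of the 12 lymphomas (circles) with the group mean and SD (bars), and for each pooled reference of the authors' deposited table (squares). Levels ran from 63.1 to 275 RPKM in Bcl6 lymphomas and from 23.3 to 298 RPKM in NIK_Bcl6 lymphomas, against a pooled 78.5 RPKM in GCB.

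Bcl6 lymphomas were compared with GCB, the normal germinal center B cells in which Bcl6 acts. Serpinb6b, a serine protease inhibitor, rose by 6.31 log2 (SE 0.61, n = 5; adjusted p = 3.92e-06 by limma), and Bhlhe41, a transcriptional repressor, by 4.78 (SE 0.44; adjusted p = 3.01e-06). Ccr6, a chemokine receptor of B cells, fell by 4.80 log2 (SE 0.86; adjusted p = 0.000507), and Rassf6, a Ras association domain gene, fell by 4.17 (SE 0.66). The other genes of largest rise were Lgals3bp (3.55), the receptor kinase gene Axl (3.32), the coactivator gene Sub1 (2.93), Ubash3b (2.84), Cd300lf (2.75), Grn, which encodes progranulin (2.73), the interleukin 6 receptor gene Il6ra (2.71) and Fxyd5 (2.71). Those of largest fall were Hjurp, a chaperone of centromeric histone (−3.32), the complement regulator Cd55 (−3.02), Arhgap4 (−2.81), Foxm1, a transcription factor for mitotic genes (−2.62), Safb2 (−2.62), Carmil2 (−2.59), the DNA helicase gene Helq (−2.58, SE 0.11) and Ccdc88b (−2.52). Every one of these 20 genes moved the same way in 5 of 5 lymphomas. Axl lost its call without Bcl6 lymphoma replicate 3 (2.75 log2, adjusted p = 0.0563). Bcl6 itself differed by 0.71 log2 (SE 0.47; higher in 3 of 5) and did not pass (adjusted p = 0.213). Gcsam, a germinal center marker, fell from a pooled 32 RPKM in the authors' deposited table. In the Bcl6 lymphomas it stood at 0.378 ± 0.564 RPKM (SD, n = 5), so close to 0 that its fold (−8.79 log2, SE 1.37) is uncertain.

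Cell cycle genes fell and antigen presentation genes rose in the Bcl6 lymphomas against GCB. Of 12 cell cycle genes 10 fell, also 10 when adjusted over the list alone (camera adjusted p = 0.0122; adjusted p = 0.530 with an estimated correlation). Among them were Cenpe, a kinetochore motor (−2.59, SE 0.31), Bub1 (−2.23), Cenpf (−1.96) and Mki67 (−1.78). Of 9 antigen presentation genes 8 rose, also 8 over the list alone (adjusted p = 0.000825; adjusted p = 0.338 with an estimated correlation), with H2-K1 at 1.23 (SE 0.20), H2-D1 at 1.12 and the class II genes H2-Eb1 at 0.99 and H2-DMa at 0.98. H2-DMa was far lower in replicate 5 than in the other lymphomas of this group. Plasma cell genes rose at 5 of 8, also 5 over the list alone (adjusted p = 0.00689; adjusted p = 0.338 with an estimated correlation), including Prdm1, the transcription factor of plasma cell differentiation (1.54, SE 0.32), Mzb1 (1.94) and the chaperone gene Pdia4 (1.95). DNA damage response genes fell at 7 of 10, also 7 over the list alone (adjusted p = 0.0417; adjusted p = 0.338 with an estimated correlation), among them the exonuclease gene Exo1 (−1.76), Trp53bp1 (−1.11), Prkdc (−1.07) and the mismatch repair gene Mlh1 (−0.93). Myeloid markers rose at 4 of 6, also 4 over the list alone (adjusted p = 0.0713, not passing), with the macrophage gene Cd68 at 2.29 (SE 0.46), Axl at 3.32, Adgre1 at 2.38 and Itgam at 2.27. Only Cd68 kept its call in every setting. Itgam lost it with 1 RPKM added (1.40, adjusted p = 0.0568), without replicate 1 (adjusted p = 0.0581), without replicate 4 (adjusted p = 0.0619) and without the pair Bcl6 replicate 1 and NIK_Bcl6 replicate 5 (adjusted p = 0.0652). Axl lost it without replicate 3 (2.75, adjusted p = 0.0563), and Adgre1 without that pair (1.80, adjusted p = 0.0511). In the authors' deposited table Axl was far higher in ABC, which are cultured B cells, than in GCB. Its rise against GCB thus does not by itself point to myeloid cells. The T cell marker Cd5 rose by 3.19 (SE 0.86), the only 1 of 4 T cell markers past the threshold, also 1 over the list alone, and Nid1 of the stroma list was at 1.65 without passing.

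Other lists did not pass against GCB in the Bcl6 lymphomas. Activated B cell genes rose at 4 of 7, also 4 over the list alone (adjusted p = 0.116), led by the adhesion receptor Cd44 (2.46, SE 0.25) and Tnfrsf13b, which encodes TACI (1.61). Interferon genes had 2 that rose, Ifih1 (2.15) and Stat1 (1.93, with replicate 2 far below the others), and 1 that fell, Rnf213 (−0.84), a call lost without replicate 2 (adjusted p = 0.0531); the counts over the list alone were 2 and 1 (adjusted p = 0.403). B cell receptor genes had 2 that rose and 5 that fell of 15, also 2 and 5 over the list alone, with Cd19 at −1.35 and Lyn at 0.94 (median −0.18, mean −0.20, test up, adjusted p = 0.926). NF-κB targets had 2 that rose and 1 that fell of 8, and 1 and 1 over the list alone (adjusted p = 0.478). Bcl6-repressed genes had 3 that rose and 3 that fell of 9, and 3 and 4 over the list alone (median −0.36, mean 0.28, test up, adjusted p = 0.478). Lymphoma-mutated genes had 5 and 3 of 21, also over the list alone, and AID targets 4 and 2 of 13, also over the list alone (adjusted p = 0.192 each). Myc and ribosome genes had 0 of 5 past either threshold (adjusted p = 0.928). Both measured genes of the alternative NF-κB pathway passed, also over the list alone, Tnfrsf13b upward and the kinase gene Chuk at −0.39, a call lost after centring and without replicate 1, 3 or 5 (adjusted p up to 0.141). In all 1232 genes passed, 451 up and 781 down, and 552 up and 676 down after centring. Of passing genes, 161 up and 330 down had a mean change of at least 1 log2, with the same sign in all 5 lymphomas.

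For the NIK_Bcl6 lymphomas against GCB the question was the same, with NIK added. Bhlhe41 rose by 5.22 log2 (SE 0.37, n = 7; adjusted p = 2.77e-07 by limma) and Ubash3b, a phosphatase that restrains antigen receptor signalling, by 4.01 (SE 0.40). Rassf6 fell by 4.85 log2 (SE 0.55) and Helq fell by 3.04 (SE 0.10; adjusted p = 4.5e-10). Further genes of largest rise were Serpinb6b (3.86), Lgals3bp (3.64), Ms4a6c (3.63), Ly6a, which encodes Sca-1 (3.45), the transcription factor gene Zbtb32 (3.41; in Bcl6 lymphomas replicate 2 stood far above the others), the acute phase gene Saa3 (3.35), the cytokine receptor gene Csf2rb (3.22) and Sub1 (2.94). Those of largest fall were Carmil2 (−3.58), Hjurp (−3.50), Ccr6 (−3.26), Foxm1 (−3.21), Cd55 (−2.88), Arhgap4 (−2.64), Ripk3, a kinase of necroptosis (−2.58), and Sipa1, a regulator of Rap (−2.46). All 20 moved the same way in 7 of 7 lymphomas. Bcl6 differed by 0.49 log2 (SE 0.39; higher in 6 of 7) without passing (adjusted p = 0.285). Gcsam stood at 0.119 ± 0.186 RPKM (SD, n = 7), with an uncertain fold of −9.85 log2 (SE 1.16).

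Cell cycle genes fell at 11 of 12 in the NIK_Bcl6 lymphomas, also 11 when adjusted over the list alone (camera adjusted p = 0.000762; adjusted p = 0.345 with an estimated correlation). Cenpe was at −3.16 (SE 0.27), Bub1 at −2.77, Mki67 at −2.42 and Cenpf at −2.38. All 9 antigen presentation genes rose, also 9 over the list alone (adjusted p = 0.000201; adjusted p = 0.310 with an estimated correlation), with H2-K1 at 1.42 (SE 0.17), H2-Eb1 at 1.21, H2-D1 at 1.20 and H2-DMa at 1.03. Plasma cell genes rose at 6 of 8, and 7 over the list alone (adjusted p = 0.00521; adjusted p = 0.310 with an estimated correlation), with Pdia4 at 2.08, Mzb1 at 1.78, Prdm1 at 1.74 and Sel1l, a part of the degradation machinery of the endoplasmic reticulum, at 1.17. DNA damage response genes fell at 7 of 10, also 7 over the list alone, with Exo1 at −1.97, Pms2 at −0.97 and Mlh1 at −0.91, while the list itself missed the threshold (adjusted p = 0.0572). Myeloid markers rose at 3 of 6, also 3 over the list alone (adjusted p = 0.0831, not passing), with the integrin gene Itgam at 4.29 (SE 0.59), Adgre1 at 2.44 and Cd68 at 1.41. The stroma gene Nid1 rose by 2.51 (SE 0.77; higher in 5 of 7), also over the list alone. Cd5 rose by 1.79 (SE 0.73; higher in 5 of 7), 1 of 4 T cell markers and 0 over the list alone, a call lost without replicate 1, 3, 5, 6 or 7 (adjusted p up to 0.134).

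In the remaining lists Cd44 rose by 2.16 (SE 0.21), Pim1, a kinase proto-oncogene, by 1.24 and Nfkbiz by 1.03 among activated B cell genes. Of these 4 rose and 1 fell, the signalling scaffold gene Card11 (−0.98), with the same counts over the list alone (7 measured, adjusted p = 0.0849). Interferon genes had 3 that rose and 1 that fell of 9, and 2 and 0 over the list alone, with Stat1 at 2.54 and Ifih1 at 2.41 (adjusted p = 0.186). Among NF-κB targets 3 rose and 1 fell of 8, the survival gene Bcl2l1 (−2.11), also over the list alone (adjusted p = 0.376). Bcl6-repressed genes had 3 and 2 of 9, also over the list alone (median −0.20, mean 0.33, test up, adjusted p = 0.376). B cell receptor genes had 4 and 5 of 15, also over the list alone, with Cd19 at −1.49 and Lyn at 1.00 (adjusted p = 0.984). Lymphoma-mutated genes had 6 and 1 of 21 and AID targets 4 and 1 of 13, each also over the list alone, with the phosphatase gene Dusp2 at −2.31 (adjusted p = 0.0831 and 0.186). The ribosome gene Pes1 (−0.42) was the only Myc and ribosome gene past the threshold, also over the list alone (median 0.17, adjusted p = 0.658). Tnfrsf13b rose by 0.67 and Chuk was at −0.38, both also past the threshold over the list alone. Tnfrsf13b lost its call in the fit of this group alone (adjusted p = 0.0629), without replicate 6, where the rise was only 0.40 (adjusted p = 0.0583), and without replicate 7 (adjusted p = 0.0743). Chuk lost its call after centring (adjusted p = 0.0608) and without replicate 1, which stood far below the others (adjusted p = 0.0512). In all 1416 genes passed, 577 up and 839 down, and 663 up and 760 down after centring. Of passing genes, 155 up and 307 down had a mean change of at least 1 log2, with the same sign in all 7 lymphomas.

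**Figure D2:**
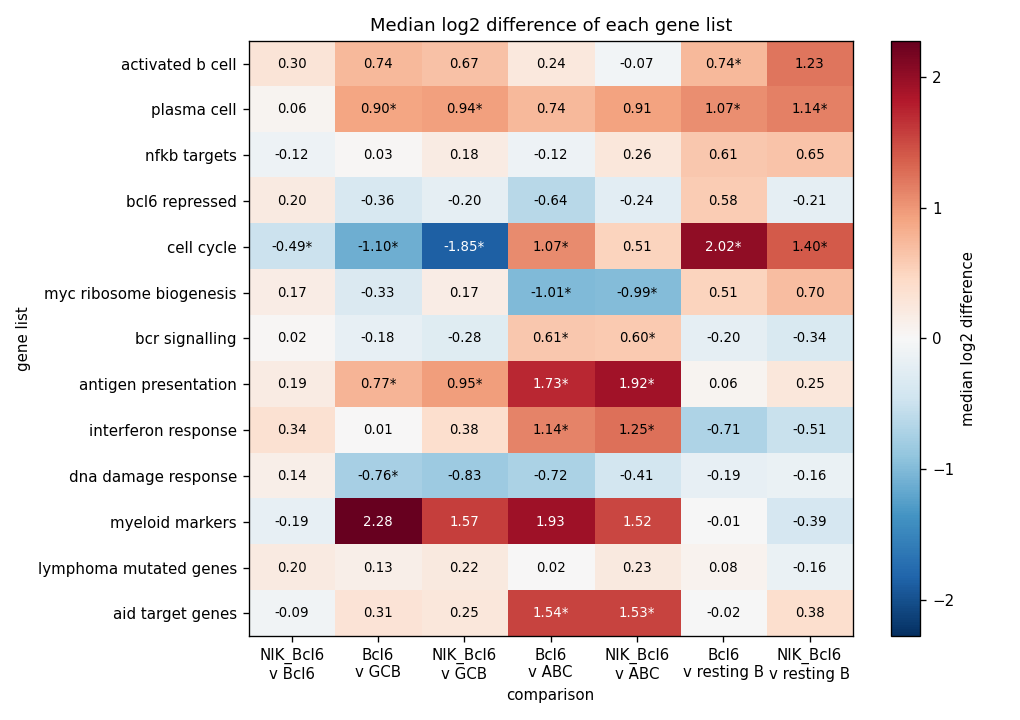
Median log2 difference of each tested gene list (vertical) in each comparison (horizontal), with an asterisk where camera passed at an adjusted p of 0.05 with the preset correlation. With an estimated correlation 0 of the 24 marked cells passed, and the cell cycle list lay at −1.10 and −1.85 against GCB and at 2.02 and 1.40 against resting B cells.

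Against ABC the lymphomas were set beside B cells activated through CD40 and the antigen receptor. Bcl6 rose by 5.68 log2 in Bcl6 lymphomas (SE 0.47, n = 5; adjusted p = 1.31e-06 by limma) and Ltb, which encodes lymphotoxin beta, by 6.74 (SE 0.48). Cyp4f18, a fatty acid hydroxylase, rose by 6.14, Cd300lf by 6.03 and Serpinb6b by 5.60. Ccr6 fell by 7.36 log2 (SE 0.86), and the genes induced by antigen receptor signals Egr2 and Nr4a1 fell by 5.06 (SE 0.50) and fell by 3.92, with Vat1 at −4.58 and Axl at −3.88. Each of these 10 genes moved the same way in 5 of 5 lymphomas. In total 1229 genes passed, 477 up and 752 down, and 576 up and 608 down after centring. Of passing genes, 243 up and 253 down had a mean change of at least 1 log2, with the same sign in all 5 lymphomas.

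All 9 antigen presentation genes rose in the Bcl6 lymphomas against ABC, also 9 over the list alone (camera adjusted p = 3.2e-07; adjusted p = 0.195 with an estimated correlation), with H2-DMa at 3.73 (SE 0.24), H2-DMb2 at 2.77 and the peptide transporter Tap1 at 1.87. Of 15 B cell receptor genes 8 rose and 1 fell, and 9 and 1 over the list alone (adjusted p = 0.00298; adjusted p = 0.195 with an estimated correlation), with the inhibitory receptor Cd22 at 3.55, the kinase gene Syk at 3.27 and Cd79b at 1.73. Myc and 4 ribosome biogenesis genes fell, 5 of 5 and also 5 over the list alone (adjusted p = 0.0123; adjusted p = 0.195 with an estimated correlation), with Myc at −1.77 (SE 0.18) and Ddx21 at −1.51. Interferon genes rose at 6 and fell at 1 of 9, also over the list alone (adjusted p = 0.0436; adjusted p = 0.387 with an estimated correlation), with the protease gene Usp18 at 2.39 and Stat1 at 1.17 (each higher in 4 of 5), while Ifih1 was at −1.77. Cell cycle genes rose at 7 and fell at 2 of 12, also over the list alone (adjusted p = 0.0436; adjusted p = 0.573 with an estimated correlation), with Mki67 at 2.24 and Tpx2 at 1.56. AID targets rose at 8 and fell at 2 of 13, also over the list alone (adjusted p = 0.00298; adjusted p = 0.177 with an estimated correlation). Plasma cell genes had 3 that rose and 1 that fell of 8, and 5 and 2 over the list alone, with Mzb1 at 2.63 (adjusted p = 0.0697). DNA damage genes had 7 that fell of 10, also over the list alone, with the uracil glycosylase gene Ung at −0.99 (adjusted p = 0.110). NF-κB targets had 2 and 3 of 8, also over the list alone, with Bcl2l1 at −3.65 (median −0.12, mean 0.47, test up, adjusted p = 0.676). Activated B cell genes had 2 and 2 of 7, also over the list alone (median 0.24, mean −0.47, test up, adjusted p = 0.676), Bcl6-repressed genes 1 and 5 of 9, and 2 and 5 over the list alone (adjusted p = 0.542), and lymphoma-mutated genes 8 and 7 of 21, and 9 and 8 over the list alone (adjusted p = 0.309). Both measured genes of the alternative NF-κB pathway missed the threshold (median 0.15), and in the germinal center list Bcl6 rose and Gcsam did not pass, also over the list alone. Myeloid markers had 3 that rose and 1 that fell of 6, and 4 and 1 over the list alone (adjusted p = 0.0935), with Cd68 at 2.31. Itgam (3.94 ± 3.06 RPKM, SD, n = 5) and Fcgr3 (1.37 ± 1.47 RPKM, SD, n = 5) also rose, Fcgr3 not with 1 RPKM added (adjusted p = 0.209). Their pooled ABC levels of 0.0437 and 0.053 RPKM in the authors' deposited table are so close to 0 that the folds are uncertain. Of T cell and stroma markers 0 passed, with medians of 0.60 and 1.89.

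How the lymphomas with NIK stand beside the same activated cells was asked next. They had Bcl6 higher by 5.47 log2 (SE 0.39, n = 7; adjusted p = 2.57e-07 by limma), Ltb by 6.81 (SE 0.41; replicate 2 stood far below the others), Cyp4f18 by 5.64, Cd300lf by 5.64 and Fgd2, an activator of Cdc42, by 5.14. Ccr6 fell by 5.82 log2 (SE 0.73), Vat1 fell by 5.22 and Egr2 fell by 4.76 (SE 0.42), with Nr4a1 at −4.16. Axl was at −5.46 (SE 0.84; lower in 6 of 7, with replicate 6 far above the others), and the other 9 genes moved the same way in 7 of 7. In total 1365 genes passed, 555 up and 810 down, and 657 up and 681 down after centring. Of passing genes, 251 up and 237 down had a mean change of at least 1 log2, with the same sign in all 7 lymphomas.

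All 9 antigen presentation genes rose in the NIK_Bcl6 lymphomas against ABC, also 9 over the list alone (camera adjusted p = 3.05e-07; adjusted p = 0.238 with an estimated correlation), with H2-DMa at 3.79 (SE 0.20) and H2-DMb2 at 3.03. B cell receptor genes rose at 7 and fell at 2 of 15, also over the list alone (adjusted p = 0.00838; adjusted p = 0.238 with an estimated correlation), with Syk at 3.95 (SE 0.21), Cd22 at 3.56 and Lyn at 1.59. Myc and ribosome genes fell at 5 of 5, also 5 over the list alone (adjusted p = 0.0163; adjusted p = 0.238 with an estimated correlation), with Ddx21 at −1.33 and Myc at −1.16. Interferon genes rose at 6 and fell at 1 of 9, also over the list alone (adjusted p = 0.014; adjusted p = 0.350 with an estimated correlation), with Oasl2 at 2.87, Usp18 at 2.12 and Stat1 at 1.78, while Ifih1 was at −1.51. AID targets rose at 7 and fell at 2 of 13, also over the list alone (adjusted p = 0.0114; adjusted p = 0.238 with an estimated correlation). Among cell cycle genes 6 rose and 2 fell of 12, also over the list alone, with Mki67 at 1.59, Tpx2 at 1.12 and the replication genes Pcna at −1.49 and Mcm2 at −1.18 (adjusted p = 0.336). Plasma cell genes had 5 and 1 of 8, and 6 and 2 over the list alone, with Mzb1 at 2.47 and Slamf7 at −1.58 (adjusted p = 0.0621). DNA damage genes had 1 and 5 of 10, also over the list alone, with Ung at −1.37 (adjusted p = 0.206). NF-κB targets had 3 and 2 of 8, also over the list alone, with Bcl2l1 at −4.43, Gadd45b at 1.82 and Nfkb1 at −1.46 (adjusted p = 0.381). Activated B cell genes had 1 and 2 of 7 (adjusted p = 0.969), Bcl6-repressed genes 2 and 4 of 9 (adjusted p = 0.626) and lymphoma-mutated genes 6 and 5 of 21 (adjusted p = 0.208), each also over the list alone, with the transcription factor gene Ikzf3 at 2.48 and Pim1 at 2.39. The alternative NF-κB pathway had 0 of 2 past the threshold (median −0.32), and of the germinal center list Bcl6 alone passed. Myeloid markers had 4 that rose and 1 that fell of 6, also over the list alone (adjusted p = 0.160). Itgam (24 ± 30.8 RPKM, SD, n = 7) and Fcgr3 (9.61 ± 21.9 RPKM, SD, n = 7) were among those that rose, with uncertain folds, since their ABC levels were close to 0. With 1 RPKM added the Itgam difference was 3.74. Fcgr3 stood far higher in replicate 5 than in the other lymphomas of this group, and Nid1 rose by 2.75, also over the list alone. Cd5 fell by 2.00 (SE 0.73; lower in 4 of 7), 0 of 4 T cell markers over the list alone, a call lost without replicate 2, 3, 4 or 6 (adjusted p up to 0.094).

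Resting B cells gave the baseline before activation. In the Bcl6 lymphomas Bcl6 rose by 1.83 log2 (SE 0.47, n = 5; adjusted p = 0.00594 by limma; higher in 5 of 5) and Serpinb6b by 6.74 (SE 0.61). The lipid carrier gene Apoe rose by 3.51, Impa2 by 3.10, the centromere gene Cenpm by 2.86 and Clip2 by 2.67. Ccr6 fell by 6.40 log2 (SE 0.86) and Cd55 fell by 4.94 (SE 0.75), with the viral RNA sensor Ddx58 at −3.14, Mndal at −2.60 and Zmynd11 at −2.59. Zmynd11 did not pass in a fit of this group alone (adjusted p = 0.0564). In total 1142 genes passed, 484 up and 658 down, and 570 up and 534 down after centring, which turned the larger share upward. Of passing genes, 178 up and 206 down had a mean change of at least 1 log2, with the same sign in all 5 lymphomas.

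Every measured cell cycle gene rose against resting B cells in the Bcl6 lymphomas, 12 of 12 and also 12 over the list alone (camera adjusted p = 1.11e-07; adjusted p = 0.321 with an estimated correlation), with the spindle kinase Ttk at 2.77 (SE 0.27), Tyms at 2.60 and Mki67 at 2.46. Plasma cell genes rose at 7 of 8, also 7 over the list alone (adjusted p = 0.00106; adjusted p = 0.298 with an estimated correlation), with Prdm1 at 2.27 (SE 0.32), Sel1l at 1.55 and Mzb1 at 1.46. Activated B cell genes rose at 4 of 7, also 4 over the list alone (adjusted p = 0.0406; adjusted p = 0.298 with an estimated correlation), with Cd44 at 2.03 and Pim1 at 1.48. Myc (0.74) and 2 ribosome genes rose of 5, and 4 over the list alone (adjusted p = 0.119). B cell receptor genes had 3 that fell of 15, and 2 over the list alone, with Cd19 at −0.93 and Cd79b at −0.78 (adjusted p = 0.528). Antigen presentation genes had 2 that rose of 9, also over the list alone, with Tap1 at 0.96 (adjusted p = 0.204). Interferon genes had 2 and 3 of 9, and 2 and 5 over the list alone, with Stat1 at 1.23 (higher in 4 of 5; adjusted p = 0.641). DNA damage genes had 2 and 3 of 10, also over the list alone, with Ung at 1.78, Exo1 at 1.69 and Trp53 at −0.66 (median −0.19, mean 0.08, test down, adjusted p = 0.884). Trp53 stood lower in replicate 2 than in the others. NF-κB targets had 4 and 1 of 8, also over the list alone, with the stress gene Gadd45b at 1.80 (adjusted p = 0.154). Bcl6-repressed genes had 4 and 3 of 9, also over the list alone (adjusted p = 0.330), lymphoma-mutated genes 7 and 8 of 21, also over the list alone, with Notch2 at −2.46 (adjusted p = 0.528), and AID targets 5 and 3 of 13, also over the list alone (median −0.02, mean 0.34, test up, adjusted p = 0.204). Chuk (−0.42) was 1 of 2 alternative NF-κB genes past the threshold, also over the list alone, a call lost after centring (adjusted p = 0.115) and without replicate 1, 3 or 5 (adjusted p up to 0.121). Of germinal center genes Bcl6 rose and Gcsam was at −6.19, also over the list alone. Myeloid markers had 1 that rose, Cd68 (2.52, SE 0.46), and 1 that fell of 6, and 1 and 0 over the list alone (median −0.01, mean −0.29, test up, adjusted p = 0.641). The 1 that fell, Fcgr3 (−2.43), lost its call after centring (adjusted p = 0.0633) and without replicate 1, 4 or 5 (adjusted p up to 0.147). T cell and stroma markers had 0 past the threshold, with medians of 0.11 and −0.37.

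The last comparison with a normal population set the NIK_Bcl6 lymphomas beside resting B cells. Bcl6 rose by 1.62 log2 (SE 0.39, n = 7; adjusted p = 0.00425 by limma; higher in 6 of 7). Serpinb6b rose by 4.29 (SE 0.51), Ubash3b by 3.42, Ms4a6c by 3.38, Zbtb32 by 3.29 and Bhlhe41 by 2.85. Ccr6 was at −4.86 (SE 0.73), Cd55 at −4.79, the glycosyltransferase gene B3gnt5 at −2.89, Pxk at −2.77 and Zfp318, a regulator of IgD expression, at −2.60. Each of these 10 moved the same way in 7 of 7 lymphomas. In total 1169 genes passed, 532 up and 637 down, and 613 up and 556 down after centring, which turned the larger share upward. Of passing genes, 158 up and 141 down had a mean change of at least 1 log2, with the same sign in all 7 lymphomas.

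Cell cycle genes rose at 12 of 12 in the NIK_Bcl6 lymphomas against resting B cells, also 12 over the list alone (camera adjusted p = 3.29e-06; adjusted p = 0.340 with an estimated correlation), with Tyms at 2.43 (SE 0.28), Ttk at 1.99 and Mki67 at 1.82. Plasma cell genes rose at 7 of 8, also 7 over the list alone (adjusted p = 0.000499; adjusted p = 0.271 with an estimated correlation), with Prdm1 at 2.47 (SE 0.27), Sel1l at 1.53 and the chaperone gene Hspa5 at 1.24. Activated B cell genes had 4 that rose and 2 that fell of 7, also over the list alone, with Pim1 at 1.96, Cd44 at 1.72 and Myc at 1.35 (adjusted p = 0.0609). Among the falls Card11 (−0.55), also a B cell receptor gene, lost its call after centring (adjusted p = 0.0661) and without replicate 1, 2, 3, 4 or 5 (adjusted p up to 0.118). Myc and ribosome genes rose at 4 of 5, also 4 over the list alone, with Npm1 at 0.70 (adjusted p = 0.0525). Antigen presentation genes rose at 4 of 9, also over the list alone, with Tap1 at 1.09 and H2-K1 at 0.58 (adjusted p = 0.0525). B cell receptor genes had 6 that fell of 15, and 5 over the list alone, with Cd79a at −1.48 and Cd19 at −1.07 (adjusted p = 0.418). Interferon genes had 2 and 2 of 9, and 2 and 4 over the list alone, with Stat1 at 1.84 and Ifih1 at 1.69 (adjusted p = 0.850). DNA damage genes had 2 and 1 of 10, and 2 and 0 over the list alone, with Exo1 at 1.48 (median −0.16, mean 0.15, test up, adjusted p = 0.788). NF-κB targets had 4 that rose of 8, also over the list alone, with Icam1 at 1.22 (adjusted p = 0.101). Bcl6-repressed genes had 4 and 1 of 9, and 4 and 2 over the list alone (median −0.21, mean 0.53, test up, adjusted p = 0.276). Lymphoma-mutated genes had 9 and 5 of 21, also over the list alone, with Notch2 at −2.17 (median −0.16, mean 0.21, test up, adjusted p = 0.292), and AID targets 5 and 3 of 13, and 7 and 3 over the list alone (adjusted p = 0.193). Both alternative NF-κB genes were lower and past the threshold, also over the list alone, Tnfrsf13b at −1.0 and Chuk at −0.41, the latter lost after centring (adjusted p = 0.0514). Gcsam was at −7.25, so 1 germinal center gene rose and 1 fell, also over the list alone. Myeloid markers had 2 that rose, Itgam (3.50) and Cd68 (1.64), and 1 that fell of 6, the lipopolysaccharide receptor gene Cd14 (−3.74), and 2 and 2 over the list alone (median −0.39, mean −0.23, test up, adjusted p = 0.738). Of T cell and stroma markers 0 passed, with medians of −0.40 and 0.49.

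The reference populations differed from each other in the authors' deposited table, which allows no test here. Between ABC and GCB 736 genes differed by at least 1 log2, 289 higher and 447 lower in ABC, in the authors' deposited table. There Axl stood at 125 RPKM in ABC against 0.799 RPKM in GCB, and Egr2 and Sub1 were higher in ABC by 4.65 and 4.47 log2 (the authors' deposited table). Vat1 and the protease gene Ide were higher in ABC by 4.28 and 3.53, while Rassf6 (−7.50), Cyp4f18 (−6.20), Ltb (−5.96), Fgd2 (−5.50), the cytidine deaminase gene Apobec1 (−5.43) and Bcl6 (−4.97) were lower, as was Gcsam, at 0.0355 RPKM in ABC, in the authors' deposited table. Of 12 cell cycle genes 1 was higher and 8 were lower in ABC by at least 1 log2 in the authors' deposited table, and of 15 B cell receptor genes 1 and 7. Interferon genes had 1 higher and 6 lower in ABC than in GCB, antigen presentation genes 0 and 3, Bcl6-repressed genes 4 and 1, activated B cell genes 4 and 2, NF-κB targets 3 and 2, Myc and ribosome genes 3 and 0, and plasma cell genes 2 and 0, in the authors' deposited table. Against resting B cells, ABC had 346 genes higher and 362 lower, with Egr2 at 5.58, Vat1 at 3.26, Casp4 at 3.15, Pfkp at 3.07, Myc at 2.51, Ltb at −7.40, Fgd2 at −5.87, Itgb7 at −5.38, Mylip at −4.39 and Bcl6 at −3.85, in the authors' deposited table. With 0.1 RPKM added the counts were 353 and 348, and with 1 RPKM added 307 and 304, in the authors' deposited table, which turned the larger share upward. The authors' deposited table had 0 of 9 antigen presentation genes higher and 6 lower in ABC than in resting B cells, 1 and 7 of 9 interferon genes, and 4 and 0 of 5 Myc and ribosome genes. GCB against resting B cells had 279 genes higher and 230 lower, with Rassf6 at 4.83, Mki67 at 4.24, Foxm1 at 4.18, the chromatin assembly gene Chaf1a at 4.14 and Kif23 at 3.62, in the authors' deposited table. These became 241 and 254 with 0.1 RPKM added, which turned the larger share downward, and 208 and 184 with 1 RPKM added, in the authors' deposited table. In GCB all 12 cell cycle genes were higher than in resting B cells by at least 1 log2, while Axl (−3.76), Bhlhe41 (−2.38), Saa3 (−2.37), Il5ra (−2.22) and Hhex (−2.20) were lower, in the authors' deposited table.

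The position of the lymphomas between ABC and GCB was measured over 288 genes higher in ABC and 439 genes higher in GCB. NIK_Bcl6 lymphomas had a mean axis value of 0.05 ± 0.38 (SD, n = 7) and Bcl6 lymphomas of −0.05 ± 0.30 (SD, n = 5). Their difference of 0.10 was smaller than the spread within either group (exact two-sided permutation p = 0.641) and was −0.01 without NIK_Bcl6 replicate 6. On the same scale, computed from the pooled values of the authors' deposited table, ABC lay at 2.63, GCB at −2.25 and resting B cells at −0.49. The 12 lymphomas lay between 34.8% and 60.8% of the way from GCB to ABC, and resting B cells at 36.2%, computed from the authors' deposited table. The axis genes were chosen by the difference between ABC and GCB, so these were bound to lie far apart on it. A place between them thus does not show that the lymphomas are an intermediate state. With the 50 genes of largest fold each way the difference was 0.39 (exact two-sided permutation p = 0.130).

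**Figure D3:**
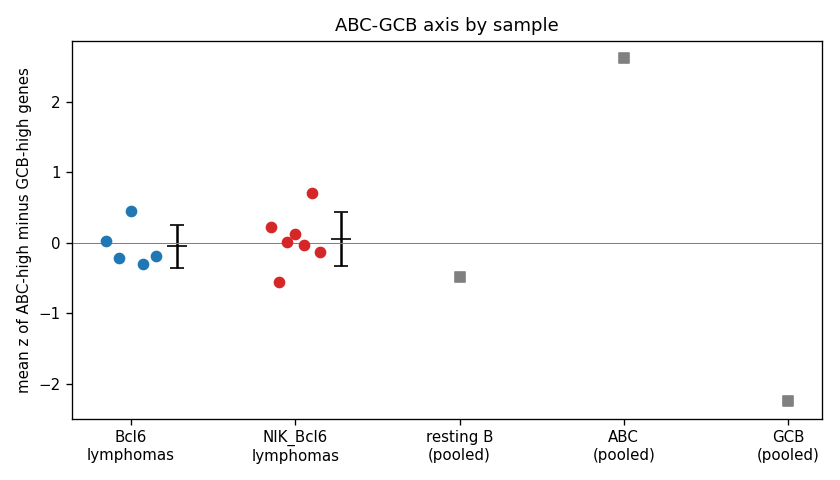
ABC-GCB axis value, a mean z over ABC-high genes minus that over GCB-high genes, for each of the 12 lymphomas (circles) with group mean and SD (bars) and for the pooled references (squares). GCB at −2.25 and ABC at 2.63 were computed from the pooled values of the authors' deposited table. They lie far apart by the choice of the axis genes.

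Candidate variants were counted per lymphoma to ask whether the NIK transgene goes with a different mutation load. NIK_Bcl6 lymphomas had 428 ± 90.6 called positions (SD, n = 7) and Bcl6 lymphomas 414 ± 83.8 (SD, n = 5). The difference of 14.1 was smaller than the spread within either group (exact two-sided permutation p = 0.788), and it was −9.39 without Bcl6 lymphoma replicate 2 and −12.6 without NIK_Bcl6 replicate 5. Called the same way against resting B cells, ABC had 198 positions and GCB 153 in the authors' deposited table. Positions called in 1 lymphoma and seen in no reference, its own positions, numbered 64.9 ± 75.6 (SD, n = 7) and 67.4 ± 44.4 (SD, n = 5). The NIK_Bcl6 mean was 37.2 without replicate 5. The share of protein-changing calls was 30.5% ± 7.85 in NIK_Bcl6 lymphomas and 30.6% ± 4.27 in Bcl6 lymphomas, a difference of −0.0667 points (exact two-sided permutation p = 0.989). The pair of lymphomas with the fewest positions with a value had the most calls. Bcl6 lymphoma replicate 1 had 2472 positions with a value and 532 calls, and NIK_Bcl6 replicate 5 had 2485 and 588.

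Bcl6 held calls at 49 positions in 10 of the 12 lymphomas, 37 of them protein-changing and 1 a stop. They are placed within the gene on chromosome 16, from 23966290 to 23977734 on NCBI 37. Of these, 42 were called in 1 lymphoma and 7 in 2. Reads of the Bcl6 transgene were not told apart from reads of this gene. The median allele fraction in carriers was 0.740, against a highest value of 0 in the references of the authors' deposited table. Bcl6 lymphomas carried 6.8 ± 5.63 such positions (SD, n = 5) and NIK_Bcl6 lymphomas 3.14 ± 3.58 (SD, n = 7), a difference within the spread (exact two-sided permutation p = 0.205). Across the 12 lymphomas the log2 Bcl6 level and the number of positions gave a Pearson r of −0.184 (permutation p = 0.562) and a Spearman rho of −0.266 (permutation p = 0.403), and r was 0.0641 without the 2 lymphomas farthest from the median level. Pim1 had 8 protein-changing positions in 6 lymphomas on chromosome 17 from 29628039 to 29628946, with allele fractions from 0.15 to 0.538. Myd88, an adaptor of Toll-like receptor signalling, carried the same protein-changing position in NIK_Bcl6 replicates 2 and 3, with allele fractions of 0.644 and 0.418. Other members of the lymphoma list with protein-changing positions were Notch2 in 3 lymphomas, with allele fractions from 0.087 to 0.167, and Kmt2c in 2 (0.2 and 0.25). Neither Kmt2c position and only 2 of the 3 in Notch2 were own positions, since the other alleles were also seen in a reference, at up to 0.0625 in the authors' deposited table. The same held for 3 Pim1 positions (up to 0.0084) and for the Cd79b position (0.0015) in the authors' deposited table. Card11 was hit in Bcl6 replicate 1 (allele fraction 0.594), Cd79b in Bcl6 replicate 5 (0.420), Kmt2d in NIK_Bcl6 replicate 5 (0.107) and Trp53 in NIK_Bcl6 replicate 3 (0.143), and Ikzf3 in Bcl6 replicate 3. The calls in Notch2, Kmt2c and Kmt2d were weak, with a deposited unadjusted p from 0.0113 to 0.0386, against at most 1.1e-22 for Myd88. By the same rule 6.05% of the positions with a value were called in ABC and 4.92% in GCB. False calls among the weak ones are thus not excluded. No bases are given in the columns used, and depth is unknown, so an allele fraction carries no interval.

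Calls fell in 1090 genes, of which 423 were hit in at least 2 lymphomas, 259 in at least 3 and 19 in all 12. With protein-changing positions 54 genes were hit in at least 3 lymphomas, and with own positions 10. Of the genes hit in all 12, Sfi1, a centrosome gene on chromosome 11 (3032881 to 3087269), and Sp110, a nuclear body gene on chromosome 1 (87475728 to 87492660), had 26 positions each, with median allele fractions of 0.308 and 0.0895. Sp140, a neighbour of Sp110, had 11 positions (median allele fraction 0.113). Tedc1 (15 positions), Esyt2 (8), Ncapg2 (8), Zfp386 (4) and Sel1l (6) lie on chromosome 12 and had a median allele fraction of 1, and all positions of the first 4 carry the table's flag of a BALB strain variant. Cd19 and the elongation factor gene Eef2 had 2 each (median allele fractions 0.121 and 0.940), tied with Mllt10. By Fisher's exact test 0 of the genes hit in at least 3 lymphomas differed between genotypes at an adjusted p of 0.05, and 5 had an unadjusted p under 0.05 (lowest 0.0101, adjusted 1). This test had little power. Genes hit in all 12 could not differ, and 1 gene split fully by genotype could not have passed after adjustment over 259 genes.

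The table holds 21 genes of the lymphoma list, and 16 were hit (76.2%), against 45.4% of the other 2368 genes (Fisher's exact p = 0.00684, two-sided). Own positions hit 9 of the 21 (exact p = 0.0669, not passing), and protein-changing positions 10 (exact p = 0.00307). Of 13 AID targets 12 were hit (92.3%; exact p = 0.000948), and 7 by own positions (53.9% against 23.8%; exact p = 0.0189). These are among 16 list tests whose p-values were not adjusted, and every gene of the table was listed for a candidate variant. Without Bcl6 the AID targets gave an exact p of 0.00187, and of 0.0442 for own positions. Of the AID targets, Cd74, Cd79a, Irf8 and Myc were hit only where a reference of the authors' deposited table showed the allele. Syk was hit only at a position called in 4 lymphomas. In the lymphoma list, Cd79a, Irf8, Myc, Stat6 and Tmsb4x were hit only at alleles seen in a reference of that table. The tests over all calls thus include alleles of normal B cells. The other genes were counted by the same rule.

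Expression in carriers of a call was compared with that in the other lymphomas over 957 genes, and the direction depended on the setting. The mean difference was 0.01 log2 (two-sided permutation p = 0.515), with a higher level in carriers for 475 genes. After centring each lymphoma it was 0.0543 (permutation p = 0.00711), a setting chosen after the data were seen. For own positions, also chosen then, it was −0.19 without centring (permutation p = 1e-05, the smallest possible) and −0.0983 with it (permutation p = 0.00348). Without Bcl6 replicate 1 and NIK_Bcl6 replicate 5, also chosen then, the difference over all calls was 0.13 (permutation p = 1e-05, the smallest possible), and with all 12 lymphomas it was, for protein-changing positions −0.14 (permutation p = 1e-05, the smallest possible), a call lost after centring (−0.0576, permutation p = 0.0697). Without that pair it was 0.03 for protein-changing positions (permutation p = 0.527) and −0.0543 for own positions (permutation p = 0.329), so neither call held. That pair held 143 and 231 own positions and had the lowest median levels over resting B cells, −0.19 and −0.285 log2. All these p-values treat genes as independent, although the same 12 lymphomas carry the calls, and do not measure the spread between lymphomas.

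**Figure D4:**
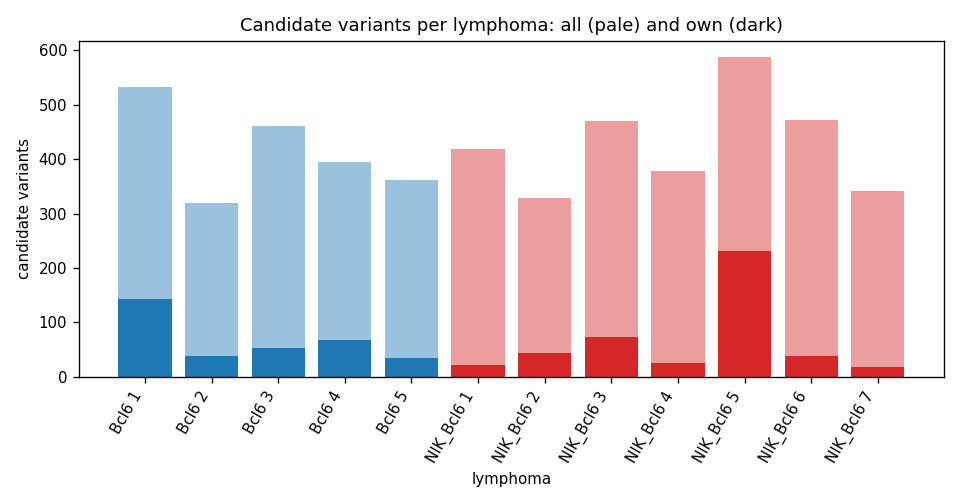
Number of called candidate positions per lymphoma (pale bars) and of those called in no other lymphoma and seen in no reference (dark bars). Calls run from 320 in Bcl6 replicate 2 to 588 in NIK_Bcl6 replicate 5, which also has the most own positions, 231.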

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

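Every observation in this part was chosen for a closer look only after the results were seen. In each lymphoma group the most extreme lymphoma was compared with the rest by Dixon's test, which marks about 5% of groups by chance, and 9 marks came from 268 checks of named genes. NIK_Bcl6 replicate 5 had a value at 2485 positions, against a mean of 2881 in the other NIK_Bcl6 lymphomas, and 231 own variants against a mean of 37.2. On the log2 scale over resting B cells, Axl stood at 3.62 in NIK_Bcl6 replicate 6 (mean of the others −2.95) and Fcgr3 at 3.87 in NIK_Bcl6 replicate 5 (−2.10). Ltb stood at −3.32 in NIK_Bcl6 replicate 2 (−0.14), and NIK_Bcl6 replicate 1 had the DNA ligase gene Lig4 at 1.5 (−0.63) and Chuk at −1.10 (−0.29). Bcl6 lymphoma replicate 2 had Stat1 at −0.19 (1.59), Trp53 at −1.47 (−0.45) and Zbtb32 at 3.71 (1.95), and Bcl6 lymphoma replicate 5 had H2-DMa at −0.78 (0.27). Calls with a BALB flag on chromosome 9 numbered 47 in Bcl6 lymphoma replicate 1, 8 in Bcl6 lymphoma replicate 4, 46 in NIK_Bcl6 replicate 1 and 38 in NIK_Bcl6 replicate 2. A run of 48 such positions in 3 genes, among them Sorl1, lies from 40824759 to 42063454, with a median allele fraction of 0.390, 0.413 and 0.306 in Bcl6 replicate 1 and NIK_Bcl6 replicates 1 and 2, and of 0 in the references of the authors' deposited table.

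The explanations of the positions called in 9 or more lymphomas were tested only after those positions had been seen. Of the 142 such positions 92 lie on chromosome 12, with a median allele fraction of 1 in carriers and 0.463 in resting B cells of the authors' deposited table. A mutation arising in the lymphomas is argued against for most of these, since 82.6% had an allele fraction of at least 0.2 in resting B cells, against 22.4% of chromosome 12 positions called in 1 lymphoma. A strain variant may explain them, as 66.3% carry a BALB flag against 6.67%; the positions are linked, so these shares carry no test. For the 50 elsewhere all 3 explanations stay open: a strain variant (0% carry a BALB flag), a mutation arising in the lymphomas (24% had an allele fraction of at least 0.2 in resting B cells, against 14% of positions called in 1 lymphoma) and reads shared between related genes (40% had a median allele fraction of at least 0.4 in carriers). In resting B cells 80% of the 50 had an allele fraction above 0, against 41% of positions called in 1 lymphoma. Their median there was only 0.0119. Depth is unknown, so whether such low fractions are real alleles cannot be told. Other explanations were not tested.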

How the results depend on the processing

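Of the alternatives below, those with 1 RPKM added, the allele fraction minimum, immunoglobulin segments or BALB flags left out, the splice-site share, the leaving out of lymphomas for the protein-changing share, own positions for genes hit in several lymphomas, the pair left out, the list tests with subsets, and, for carriers, centring and own positions were chosen only after the data were seen. No paired analysis was possible because nothing in the labels pairs a lymphoma with another sample, and the references are pooled. Of 326 named gene and comparison pairs 318 passed the threshold; 36 lost it in some setting, 32 of them with 1 lymphoma left out, and 0 changed sign. The Bcl6 difference between lymphoma groups ran from −0.49 to 0.17 with 1 lymphoma left out. Of the 24 list and comparison pairs past the threshold 0 passed with an estimated correlation. Between the lymphoma groups 0 lists passed with an estimated correlation, and 0 (without NIK_Bcl6 replicate 6) to 1 with 1 lymphoma left out. With 1 lymphoma left out the axis difference ran from −0.0106 (without NIK_Bcl6 replicate 6) to 0.22 (without Bcl6 replicate 3), and it was 0.39 with the 50 genes of largest fold each way. The difference in called positions, 14.1, was −15.4 with a stricter p, −4.26 with an allele fraction of at least 0.2, −2.54 for own positions, −16.8 for own positions with that allele fraction (exact permutation p = 0.109) and −11.3 for own positions without the pair of lymphomas with the fewest positions with a value. It was 30.9 without immunoglobulin segments, 18.1 counted in genes and 8.2 without BALB flags. With 1 lymphoma left out it ran from −12.6 (without NIK_Bcl6 replicate 5) to 43.6 (without Bcl6 replicate 1). The splice-site share differed by 1.43 points, and the protein-changing share by −2.58 (without NIK_Bcl6 replicate 5) to 1.42 (without NIK_Bcl6 replicate 6). Genes hit in at least 3 lymphomas, 259, numbered 54 with protein-changing positions, 26 with positions called in 1 lymphoma and 10 with own positions. The expression difference of carriers, 0.01, was −0.14 for protein-changing positions, −0.0576 for these after centring (permutation p = 0.0697), −0.00498 with 1 RPKM added, 0.0543 after centring (permutation p = 0.00711), −0.19 for own positions, −0.10 for these after centring (permutation p = 0.00348), −0.19 for these without immunoglobulin segments, 0.13 without the pair named above and −0.0543 for own positions without it (permutation p = 0.329). These values changed with the setting and with that pair of lymphomas, and the cause was not tested. Own positions in the lymphoma list gave an exact p of 0.0669, and of 0.0529 for protein-changing ones without Bcl6.

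The regroupings of the NIK_Bcl6 and Bcl6 comparison were drawn only after its result was seen. Of 100 splits of the 12 lymphomas into 7 and 5, at an unadjusted p under 0.05 16 had at least the real 154 genes, and the highest count was 328. For gene lists 76 of 100 had at least the real 1, with up to 6. At an adjusted p under 0.05 the real count was 0 by limma, which all 100 splits match by necessity (up to 5), so that count tests nothing. Chance is not excluded for the 154 genes or the 1 list, and some unlabelled structure among the lymphomas may underlie the 328.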

Other observations

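These observations on variants were picked out only after the variant counts had been seen. Immunoglobulin and T cell receptor segments held 180 own positions in 70 genes, with at most 16 in 1 gene, against 42 in Bcl6 and at most 6 in any other gene. Pim1, a known off-target of AID, had own positions in 4 lymphomas. Dmxl1, Myo18a and Tshz1 had own positions in 3 lymphomas each. Azin1, whose transcript is a known substrate of RNA editing, was called in 11 lymphomas at 1 position, 38421367 on chromosome 15, with a median allele fraction of 0.127.

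The explanations of the Bcl6 positions were likewise tested only after the positions were seen. Calling power in a highly expressed gene does not account for the count, since the 136 other genes outside immunoglobulin and T cell receptor segments at or above the level of Bcl6 held at most 2 own positions. Strain or transgene sequence shared by the lymphomas would recur, and no Bcl6 position was called in more than 2 lymphomas. That speaks only to a fixed shared sequence. Changes arising in the transgene of single lymphomas were not told apart from changes in the chromosome 16 gene. Reads of a related gene would show in normal cells too, yet the highest allele fraction there was 0 in the authors' deposited table. Somatic hypermutation may have acted on the gene or on the transgene. Own positions were also more frequent in the other AID targets (50% against 23.8%, Fisher's exact p = 0.0442, 1 of 16 unadjusted tests). No bases were at hand to test the signature of hypermutation.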
